A study of Mus musculus with 115 samples.

How the data were processed

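Accessibility at inserted constructs was measured by amplicon NOMe-seq in mouse 129S6/SvEvTac embryonic stem cells, in 115 libraries with 128 files. Per the labels' protocols, DNA was extracted with phenol and chloroform, bisulfite converted and amplified, and libraries were made with a NEBNext kit. Reads were trimmed with Trimmomatic 0.32, per the submitters' processing notes. Per the labels, a FASTA file is named for each of the pools that have one. The aligner, the methylation caller, any coverage filter and the genome build were not given in the sources used here. The deposited values are a fraction per cytosine position of each construct, the share of reads called methylated, and carry no counts. Depth per library was therefore unknown, and no confidence interval or lower limit of detection is given. The design foresaw read counts, so the form it named for fractions was used. Of 21621 values, 636 were missing. In the 13 libraries of the NRF1, BANP and REST groups all 874 values had at most 1 decimal, against 0.184% of values in the other pools.

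Before the data were examined, the groups, the tests, the motif lists, the rule for named constructs and most alternatives were fixed. The rule named, per class, up to 10 constructs with the largest gain and 5 with the largest loss past the threshold in the same direction in every replicate, the 5 highest that did not pass, the constructs of a fixed set of factors, and, for tiles, the highest and lowest positions of each motif. GCH sites with a value in every library of a group were used. A level was the mean over these sites of the amplicon, and its M-value was log2((f + 0.01)/(1 − f + 0.01)). The reference was the control construct of the pool, or the pool's median construct where it had none. Differences from it within a library were tested with limma 3.58.1 in R 4.3.3, with moderated spread and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. A difference of at least 10 percentage points was called large. The nuc and non_nuc classes were compared in limma by the difference of these within-library differences. BANP and REST libraries were compared per site in limma, with exact permutation tests of region means. Lists were tested with 100000 permutations, two-sided, over 12 lists and families for each measure: the pluripotency, promoter and signal-responsive lists and the families with an adjusted p in the results. The insulator and lineage lists were too small to test. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

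After the data were seen, the amplicon was divided, because a low window and high flanks offset each other in its mean. In the unphased, nuc and non_nuc classes, the window lay in a gap between neighbouring sites shared by at least 90% of the class's constructs. The gap that held the most other sites was used. For tiles, and so for the REST and BANP libraries, the window spanned the sites not shared by every construct of the same tile and backbone. The flank held the sites within 40 bp on either side. The sites called anchor sites, a stretch shared by the constructs with low methylation, were left out of flanks and were also picked after the data were seen. Windows ran from 127 to 154 in the unphased class, from 176 to 203 in nuc and non_nuc, and at tile 5 from 213 to 240. The sites in a window differ between constructs, so window levels are not means over the same positions. Flanks and windows were tested in limma against the pool's reference, its construct without a motif where it held one and otherwise its median. They were also tested against the partner named "_r" and against the construct without a motif (2 groups of libraries). The 2 groups were treated as unpaired even where both constructs were in the same pool, as CTCF and REST in nuc and non_nuc. In many tests limma gave each construct the same standard error, so these calls rest on a spread shared by all constructs. This held for unphased flanks against the construct without a motif (0.155), unphased flanks and windows against the partner, non_nuc tests against the construct without a motif or the partner, nuc flanks and windows against the construct without a motif, nuc against non_nuc at flanks and windows, the NRF1 amplicon and the sites of BANP. Without counts, the alternatives on coverage and on count models were not run. Construct profiles present in 2 pools with identical values (nucleosomal_ARNTL and unphased_MAX::MYC) were counted once. Positions of the NRF1 libraries were shifted by 48 bp, which matched 19 sites of the same construct in another pool.

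Whether replicate numbers pair libraries was checked by the correlation of deviations from the group means. For REST, same-numbered libraries correlated at 0.134 to 0.157, over 0.1 in each of 3 pairs, so the blocked count stands beside the result. These correlations over 23 sites are weak and do not establish pairing. The labels give no source for a pairing, and BANP, at 0.103 in 2 pairs, would meet the same limit. Other classes were not taken as paired. The tests were run on simulated data with 1.5 (log2) changes, of which 97% or more were found in each comparison simulated except BANP, at 1.25%. The noise was simulated as independent with a common spread. Amplicon effects were smaller, at most 0.375 in nuc, 0.324 in non_nuc and 0.625 in nuc against non_nuc (log2, without sign). The simulation therefore does not show that effects of that size would be found. The CGH files of BANP and REST were compared with the GCH files and, since the values they share are equal, their REST and BANP levels stand in the closing part only as an alternative and not as separate evidence. The values of 1 motif are not reported here.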

Results

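The data were amplicon NOMe-seq profiles of a transgenic insertion site in cells labelled as mouse 129S6/SvEvTac embryonic stem cells. NOMe-seq treats nuclei with a GpC methyltransferase, which methylates cytosines where DNA is accessible, so that GCH methylation (GC followed by A, C or T) reads accessibility. Each construct carried a transcription factor motif, or none, in a defined sequence at the recombinase-mediated cassette exchange site. There were 115 libraries in 45 groups. The unphased class held 18 pools with 2 libraries each (36 libraries, 122 constructs). The non_nuc class held 3 pools and 9 libraries (24 constructs), the nuc class 5 pools and 15 libraries (24 constructs), and the tiles class 14 pools and 42 libraries (102 constructs). A pool of 4 NRF1 constructs had 3 libraries. A construct with a BANP motif was measured with DMSO and with dTAG (2 libraries each), and a construct with a REST motif in the groups named REST_ES and REST_NP (3 libraries each). The median methylation level per library lay between 37.1% and 62.3% in the unphased class, 41.5% and 60.6% in non_nuc, 37.4% and 61.0% in nuc, and 44.6% and 63.2% in the tiles. Read depth was unknown, because the files give fractions without counts. Positions are counted along the amplicon, whose genome coordinates were not given in the sources used here. Nothing in the labels says that replicates were separate cultures, so the p-values may measure technical spread.

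In the unphased class, the sites flanking a CTCF motif (CTCF is the zinc finger protein of insulators and loop anchors) were 87.5% ± 3.93 (SD, n = 2) methylated, against 41.9% ± 1.24 (SD, n = 2) in the construct without a motif. Flanks rose to 83.4% ± 1.55 (SD, n = 2) beside REST, a repressor of neuronal genes, and to 76.7% ± 4.36 (SD, n = 2) beside BANP, which binds CpG island promoters. Inside the motif window (positions 127 to 154) the REST construct was 7.45% ± 0.524 (SD, n = 2) methylated and the CTCF construct 32.6% ± 1.79 (SD, n = 2), both lower than the 42.1% ± 0.487 (SD, n = 2) without a motif. The BANP window was 42.7% ± 2.16 (SD, n = 2) and did not pass the test. Smaller flank levels past the test were those of SP2 at 58.0% ± 3.44, the metal-responsive factor MTF1 at 57.0% ± 4.31, SRF at 53.5% ± 0.531, ZFP143 at 53.05% ± 0.855, RFX2 at 52.3% ± 1.40 and the tumour suppressor TRP53 at 52.1% ± 12.5 (SD, n = 2 each).

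Of 121 unphased constructs compared with the construct without a motif, 46 passed limma's test at the flanks, 18 higher and 28 lower. Of the 18, 9 were higher by at least 10 percentage points: BANP, CTCF, MTF1, REST, RFX2, SP2, SRF, TRP53 and ZFP143. The SD of TRP53 between its 2 libraries was 12.5, above that limit, so its place in this list is uncertain. Both a higher flank and a lower window were found for 5 constructs: CTCF, MTF1, REST, RFX2 and ZFP143. The lowest flank among the constructs named here was that of the homeodomain factor PKNOX1 at 27.5% ± 0.611 (SD, n = 2), which passed the test as lower. The flank of the pluripotency factor SOX2, at 32.99% ± 0.349 (SD, n = 2), was lower than without a motif (limma adjusted p = 0.00357) but did not pass against the median of its pool (adjusted p = 0.118) or against its partner SOX2_r at 34.4% (adjusted p = 0.864). Against the median construct of the same pool, 12 flanks passed, 5 higher and 7 lower. BANP, CTCF, KLF5, REST and ZFP143 were higher by both references, while MTF1, RFX2, SP2, SRF and TRP53 did not pass against the pool. The pool of CTCF held only CTCF and CTCF_r, so there the pool reference compares CTCF with CTCF_r alone. The construct without a motif was the only construct of its pool, so every comparison with it was also one between pools, and its 2 libraries served all of them, so errors in them are shared. The NRF1 construct was measured in a further pool, where its flank was 34.4% ± 3.85 (SD, n = 3) in place of 47.2% ± 1.84 (SD, n = 2), a gap above the 10 percentage points called large, so the smaller differences given here may be ones between pools. Flanks and windows were chosen as measures after the data were seen. With a block for the replicate number, the count of windows past the test went from 59 of 121 to 27. Leaving out replicate 1 or replicate 2 gave 87 or 82 flanks in place of 46, and 110 windows in both cases. In these fits each construct has 1 library and the spread comes from the 2 libraries without a motif alone, so they say nothing about stability.

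Further factors of interest in ES cells were closer to the level without a motif. The composite POU5F1::SOX2 motif, bound by a core pair of pluripotency factors, had a flank of 45.2% ± 2.32 (SD, n = 2; limma adjusted p = 0.329), while its window fell to 24.4% ± 3.75 (SD, n = 2; limma adjusted p = 0.00522). Flanks were 47.2% ± 1.84 for NRF1, 45.6% ± 5.65 for YY1, 43.6% ± 5.86 for POU5F1B, 37.2% ± 1.80 for ESRRB and 36.6% ± 1.40 for KLF4 (SD, n = 2 each), and of these none passed limma's test. Over the amplicon, the POU5F1::SOX2, NRF1, POU5F1B, TRP53, YY1, SOX2, ESRRB and KLF4 constructs lay between 43.4% and 47.9%, and none passed.

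For 14 motifs there was a partner construct of the same name ending in "_r", which the labels do not define, and each motif was tested against it. Flanks beside BANP, CTCF and REST were higher than beside the partner by 28.2, 45.4 and 34.5 percentage points, and these were the 3 of 14 pairs past limma's test. In the window, 6 of 14 pairs passed. REST at 7.45% ± 0.524 was lower than its partner at 57.3% ± 8.38 (SD, n = 2 each), as were BANP, ESRRB, POU5F1::SOX2 and TRP53 relative to theirs, while POU5F1B at 46.7% ± 7.47 was higher than its partner at 32.3% ± 0.930 (SD, n = 2 each). ESRRB and its partner were in different pools, so their difference is also one between pools. The CTCF window did not pass against its partner (32.6% and 41.3%, limma adjusted p = 0.0539). It also did not pass against the median of its pool (limma adjusted p = 0.0869). That pool held only CTCF and its partner, so this is the same comparison and not a second one.

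**Figure D1:**
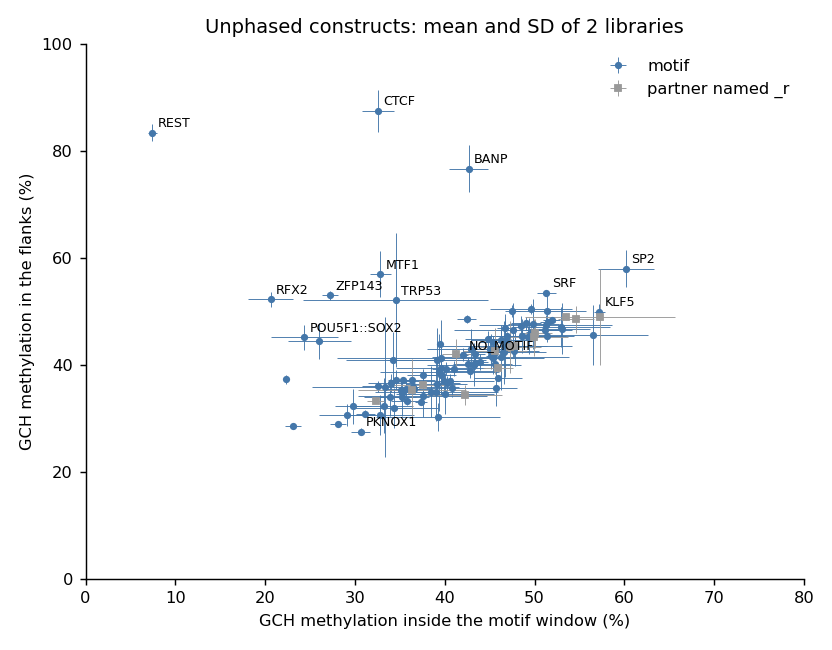
Methylation in the flanks (vertical axis, %) against methylation inside the motif window (horizontal axis, %) for the unphased constructs, as means with SD of 2 libraries. The CTCF, REST and BANP constructs lie at 87.5%, 83.4% and 76.7% in the flanks, above the 41.9% of the construct without a motif.

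Over the whole amplicon, the measure chosen before the data were examined, BANP was highest at 65.7% ± 1.29 (SD, n = 2), which was 15.01 ± 1.35 percentage points above the reference of its pool. REST rose by 10.4 ± 1.75 percentage points to 56.3%, KLF5 by 8.35 ± 0.302 to 51.2% and CTCF by 7.37 ± 0.644 to 64.4% (SD, n = 2 each). Methylation was lower by 10 percentage points or more for PKNOX1, at −10.3 ± 1.20, and ZFP423, at −10.04 ± 1.13, and it was also lower for MAFG at −9.81 ± 0.575, for the growth regulator MYC at −8.56 ± 0.118 and for the TGF-beta effector SMAD3 at −8.01 ± 2.49 percentage points (SD, n = 2 each). CTCF_r and ARID3B were also lower. In all, 12 of 120 constructs passed limma's test, 4 higher and 8 lower, with 35 at an unadjusted p under 0.05. CTCF and CTCF_r were the only constructs of their pool, whose median is the reference, so their differences mirror each other by construction. The highest levels that did not pass were 54.4% ± 0.583 for SP2, 53.4% ± 2.22 for SRF, 53.3% ± 0.519 for ZFX, 52.9% ± 0.240 for GBX2 and 52.1% ± 1.03 for ETV6 (SD, n = 2 each), against 48.0% ± 1.24 (SD, n = 2) without a motif. Among the partners of the factors named here, levels ranged from 43.3% for POU5F1B_r to 51.9% for REST_r. The amplicon mean adds a window of low methylation to flanks of high methylation.

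No list of motifs fixed before the data were examined differed from the other unphased constructs. Of 12 pluripotency motifs measured, 3 passed the amplicon test over all constructs and 3 adjusted over the list alone. Their mean difference from the reference was −0.33 percentage points relative to the others (permutation p = 0.779), and at the flanks, where 1 rose and 5 fell, it was −4.63 (permutation p = 0.0988, adjusted p = 0.759). The 16 promoter factors differed by 1.70 percentage points over the amplicon (permutation p = 0.111) and 3.60 at the flanks (permutation p = 0.150), with 1 called over all constructs and 1 adjusted over the list alone. The 12 signal-responsive motifs differed by 0.03 and −0.21 percentage points (permutation p = 0.980 and 0.942), with 1 called over all constructs and 1 adjusted over the list alone. Among motif families, KLF or SP (KLF4, KLF5, SP1, SP2 and SP3) had a mean 4.15 percentage points above the others (permutation p = 0.0264, adjusted p = 0.317 over 12 tests), with 1 called over all constructs and 3 adjusted over the list alone. For the POU, FOX, ETS, bZIP, bHLH, nuclear receptor, STAT and E2F families the adjusted p lay between 0.734 and 0.980 over the amplicon and between 0.759 and 0.814 at the flanks. The insulator and repressor list held 2 measured motifs, CTCF and REST, which both rose, and the lineage list held 2, PAX6 and TCF7, of which none passed limma's test. Both were too small to test, as were the SOX, RFX, TEAD, IRF, SMAD, PAX and p53 families, while the GATA, HOX, RUNX, TBX and NFI families had 0 constructs. Constructs are not independent replicates.

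In the non_nuc context, flanks of CTCF were 81.8% ± 6.35, of SRF 81.6% ± 8.42, of BANP 81.2% ± 6.13, of REST 80.04% ± 4.03 and of ARNTL, a component of the circadian clock, 76.8% ± 6.48, against 60.5% ± 5.39 without a motif (SD, n = 3 each). Windows (positions 176 to 203) fell to 13.1% ± 6.56 for REST, 19.5% ± 7.82 for CTCF, 23.0% ± 6.34 for RFX2, 31.9% ± 9.01 for the OctSox motif, 32.1% ± 10.2 for TRP53 and 35.6% ± 4.75 for BANP, from 67.1% ± 4.66 without a motif (SD, n = 3 each). Edge sites raised some of these means, as at position 203, with 47.8% ± 9.30 for CTCF and 80.1% ± 2.51 for BANP (SD, n = 3 each). The SRF window was 72.7% ± 14.2 and the ARNTL window 68.1% ± 8.97 (SD, n = 3 each), and neither passed. The OctSox flank was 63.6% ± 4.12 and the TRP53 flank 68.3% ± 8.54 (SD, n = 3 each), and neither passed.

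The 5 constructs named first were those past limma's test at the flanks among 23, all higher, and 10 passed when replicate 1 was left out. SRF did not pass against the median of its pool (limma adjusted p = 0.0731), while ARNTL and BANP of that pool did. CTCF and REST shared a pool with the construct without a motif, which was again their reference there. Their pass is therefore no second comparison. In the windows 14 of 23 passed, all lower, but the construct without a motif had 1 site in its window. BANP, CTCF and REST were also higher than their partners at the flanks, but only BANP and its partner were in the same pool, so the other pairs also differ in pool. Over the amplicon, 2 of 23 passed limma's test, ARNTL at 4.36 ± 3.68 and SRF at 5.59 ± 7.08 percentage points above the pool's reference (SD, n = 3 each; adjusted p = 0.0347 and 0.00438), with 4 at an unadjusted p under 0.05. Both passed without replicate 1, but neither passed without replicate 2 or without replicate 3 (where 1 other construct, OctSox, passed). Their pool had no control, so its median was already their reference. When the median was used for every pool, neither passed, although their own differences were the same. The fit then held 24 constructs in place of 23. Among the highest amplicon levels that did not pass were 56.1% ± 6.50 for BANP, 55.5% ± 0.836 for TRP53_r, 54.7% ± 3.95 for E2F7 and 54.2% ± 6.60 for BHLHE40, and the level without a motif was 50.8% ± 5.54 (SD, n = 3 each). CTCF, REST, OctSox and TRP53 had amplicon levels of 52.8%, 51.3%, 54.04% and 52.6%, and the partners BANP_r, CTCF_r, OctSox_r and REST_r lay between 52.2% and 54.1%.

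In the nuc context, flanks rose to 89.5% ± 2.37 for CTCF, 83.9% ± 2.61 for REST, 71.5% ± 4.54 for BANP, 63.1% ± 0.407 for TRP53 and 58.7% ± 6.17 for OctSox, from 45.9% ± 3.75 without a motif (SD, n = 3 each). They fell to 31.8% ± 3.87 for BANP_r and 34.2% ± 3.41 for ZFP423 (SD, n = 3 each). In the windows, REST at 10.2% ± 0.886, CTCF at 15.5% ± 1.26 and RFX2 at 12.5% ± 2.83 were lower than the 28.3% ± 4.80 without a motif, while BANP at 22.3% ± 7.51, TRP53 at 27.6% ± 1.17 and OctSox at 19.6% ± 1.53 did not pass (SD, n = 3 each). Flanks were higher than the partner's by 45.1 percentage points for CTCF, 39.7 for BANP, 36.3 for REST, 15.6 for TRP53 and 14.9 for OctSox, which were 5 of 6 pairs. Windows passed against the partner for 3 of 6 pairs, CTCF and REST lower and BANP higher, by 8.74 percentage points. The BANP mean includes the 58.4% at position 203. BANP and its partner have 4 and 3 window sites, so the 2 means do not cover the same positions. Only BANP and its partner were in the same pool, so differences between pools may enter the other pairs.

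In limma, 8 of 23 nuc flanks passed, 6 higher and 2 lower, and 6 of 23 windows, all lower, or 11 without replicate 2 and 4 without replicate 3, where the CTCF window did not pass. At the flanks ZFP423 did not pass without replicate 3, and OctSox not without replicate 2 or 3. OctSox, in a pool of 2 constructs, also did not pass against the median of its pool (limma adjusted p = 0.842). Over the amplicon 0 of 23 passed limma's test, with 1 at an unadjusted p under 0.05. Among the highest amplicon levels were 58.4% ± 2.66 for OctSox, 54.4% ± 1.26 for CTCF, 53.7% ± 3.44 for SRF and 52.9% ± 0.796 for TRP53, and the level without a motif was 53.2% ± 2.53 (SD, n = 3 each). REST had 52.2% and BANP 51.1%, and their partners and those of CTCF, OctSox and TRP53 lay between 45.9% and 52.3%.

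**Figure D2:**
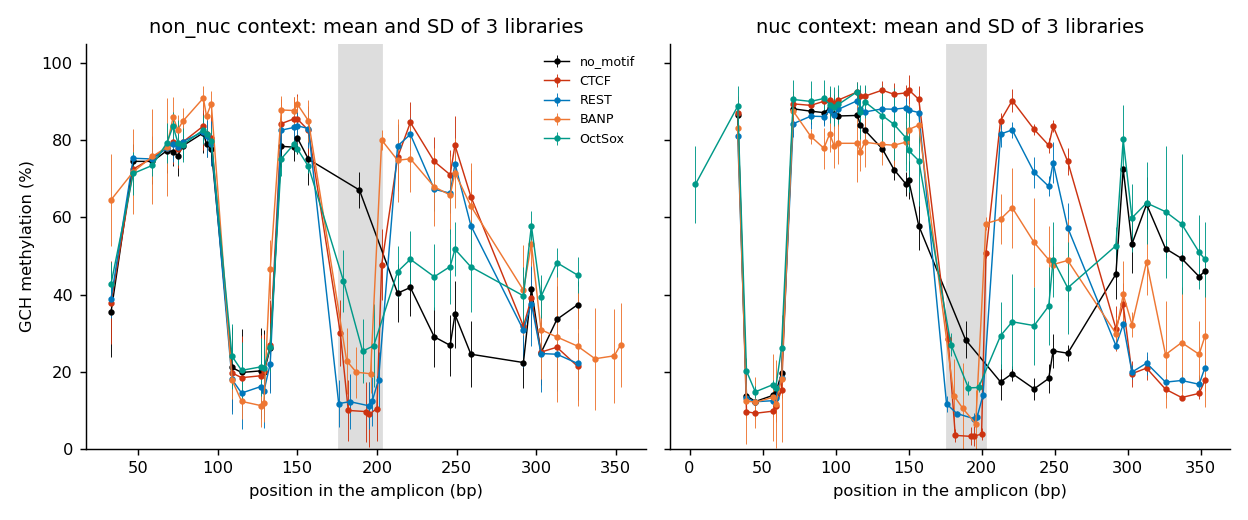
GCH methylation (vertical axis, %) along the amplicon (horizontal axis, bp) for 5 constructs in the non_nuc and nuc contexts, as means with SD of 3 libraries, the motif window in grey. In the nuc context the CTCF flanks average 89.5% and those without a motif 45.9%.

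The nuc and non_nuc contexts were compared by the effect of each motif over the construct without a motif of its own class. At the flanks CTCF added 43.6 percentage points in nuc and 21.3 in non_nuc, a difference of 1.67 ± 0.35 (log2, SE, n = 3 per class), and REST added 38.1 and 19.5, a difference of 1.20 ± 0.35 (log2, SE, n = 3 per class). ARNTL and SRF went the other way, with −3.52 and 5.52 percentage points in nuc against 16.3 and 21.1 in non_nuc, differences of −1.32 ± 0.35 and −1.28 ± 0.35 (log2, SE, n = 3 per class). These were the 4 of 23 motifs past limma's test of the difference (adjusted p = 6.2e-05, 0.00359, 0.00207 and 0.00219). Of these, CTCF and REST passed without replicate 1, ARNTL, CTCF and SRF without replicate 2, and ARNTL and CTCF without replicate 3, so only CTCF passed each time. The SRF difference rests on a non_nuc flank that did not pass against the median of its pool (limma adjusted p = 0.0731). In both classes CTCF and REST shared a pool with the construct without a motif, while ARNTL and SRF were in another pool. The ARNTL and SRF effects are therefore also differences between pools. BANP added 25.6 and 20.6 percentage points, and this difference did not pass (limma adjusted p = 0.999). The flank without a motif started at 60.5% in non_nuc and 45.9% in nuc, and CTCF brought it to 81.8% and 89.5%. At positions 140 and 157 the level without a motif was already 78.5% and 75.1% in non_nuc, against 72.4% and 57.8% in nuc. A higher start may therefore add to the smaller CTCF and REST gains in non_nuc, which was not tested. In the windows, 8 of 23 motifs differed between the contexts, among them BANP, CTCF, MTF1, OctSox, REST, RFX2 and TRP53, or 13, 5 and 3 without replicates 1, 2 and 3, where CTCF, REST and TRP53 passed each time. The window without a motif was 28.3% in nuc and 67.1% in non_nuc, each from 1 site, and for each of the 8 motifs the drop from it was smaller in nuc. In nuc and non_nuc the CTCF windows were 15.5% and 19.5%, those of REST 10.2% and 13.1% and those of BANP 22.3% and 35.6%. The differences therefore rest largely on the window without a motif. Over the amplicon 0 of 23 motifs passed limma's test, with 2 at an unadjusted p under 0.05, and 1 passed without replicate 2.

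The tiles class placed 5 motifs at up to 7 positions in a CTCF backbone and a REST backbone. In the CTCF backbone, flanks of the CTCF motif were 91.1% ± 6.21 at tile 2 and 66.3% ± 2.15 at tile 4, its highest and lowest positions, and those of REST were 91.6% ± 1.60 at tile 2 and 69.8% ± 8.51 at tile 5 (SD, n = 3 each). BANP ranged from 78.9% ± 10.6 at tile 1 to 56.1% ± 2.91 at tile 4, OctSox from 88.9% ± 1.69 at tile 1 to 35.7% ± 6.71 at tile 5, and BHLHE40, a circadian repressor, from 84.8% ± 4.57 at tile 2 to 44.8% ± 3.50 at tile 5 (SD, n = 3 each). In the REST backbone, CTCF ranged from 89.6% ± 4.02 at tile 2 to 63.6% ± 6.81 at tile 4, REST from 88.4% ± 4.14 at tile 2 to 61.5% ± 3.04 at tile 6, and BANP from 86.1% ± 2.09 at tile 2 to 56.4% ± 1.22 at tile 6 (SD, n = 3 each). OctSox ranged there from 87.1% ± 0.878 at tile 2 to 32.5% ± 2.23 at tile 4, and BHLHE40 from 87.2% ± 3.80 at tile 1 to 37.3% ± 2.82 at tile 4 (SD, n = 3 each).

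Against the "_r" partner at the same tile, available at tiles 2 to 5, flanks were higher for 18 of 32 pairs in limma. CTCF was higher in 6 of 8 pairs, with differences of 8.07 to 38.9 percentage points over the 8, and REST in 7 of 8, with 6.42 to 49.8. With a flank of 20 bp the effect of CTCF turned at tile 4, from 1.62 to −0.22 (log2) in CTCF_tile4_CTCF and from 1.82 to −0.27 in REST_tile4_CTCF, and 14 of 32 pairs passed. OctSox was higher in 4 of 8, with −3.64 to 21.7, and BHLHE40 in 1 of 8, with −9.98 to 16.4. Windows passed for 19 pairs, of which 18 were lower: 7 for CTCF, 5 for REST, 4 for BHLHE40 and 2 for OctSox. With a replicate block 11 windows passed, and 7, 9 and 11 passed without replicates 1, 2 and 3. Partners of a pair were not always in the same pool.

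Averaged over both backbones, the flanks of the CTCF partner were 67.3% at tiles 2 and 3 and 37.4% at tiles 4 and 5, and those of the REST, OctSox and BHLHE40 partners were 72.4% and 33.7%, 64.5% and 30.2%, and 72.5% and 39.1%. The flank gain of a motif over its partner went from 15.2 to 32.7 percentage points for CTCF and from 12.4 to 38.5 for REST, and from 15.7 to 9.01 for OctSox and from 7.96 to 4.46 for BHLHE40. The change in gain was 26.9 percentage points higher for CTCF and REST than for OctSox and BHLHE40. This grouping of tiles and motifs was chosen after the values were seen, and 2 motifs against 2 cannot give an exact permutation p below 0.3333, so the difference is given as a value with no test. The REST constructs at tiles 3 and 4, and at tile 5 of the CTCF backbone, were all in pool 6, and their partners were in other pools. Anchor sites of the REST constructs ranged from 19.2% to 40.2% in pool 6, against 4.35% to 13.5% in pools 2 and 4, so a raised background may add to the REST gains of 41.9 and 49.8 percentage points at tile 4 and 34.3 at tile 5. At tiles 4 and 5 the only REST pair within a pool was REST_tile5_REST, with a gain of 28.1, and at tile 2 the pairs within a pool gained 13.4 and 12.97. The CTCF pairs within a pool gained 8.07 and 11.8 at tile 3, 30.8 at tile 4 and 38.9 and 33.3 at tile 5. For OctSox, pool 6 held the motif of CTCF_tile4_OctSox and REST_tile5_OctSox (gains 21.7 and 12.5), with partners in other pools. It also held the partner of CTCF_tile3_OctSox and REST_tile4_OctSox (gains 18.9 and −3.64), with the motif in other pools. The background of pool 6 may therefore enter the OctSox values too. The OctSox pairs within a pool gained 12.9 and 20.9 at tile 2 and 5.46 at tile 5. The CTCF gains at tile 4 rest on the flank of 40 bp, since CTCF_tile4_CTCF and REST_tile4_CTCF turned to −0.22 and −0.27 (log2) with 20 bp. Over all 7 tiles, 20 rank correlations of each measure with position or with the distance from the middle gave none past adjustment. The lowest adjusted p was 0.127, for BHLHE40 over the amplicon in the CTCF backbone (Spearman's rho = −0.918, Pearson's r = −0.88, exact permutation p = 0.00635).

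Over the amplicon, 2 of 100 tiled constructs passed limma's test, REST_tile2_REST_r at 56.2% and REST_tile6_REST at 39.7%, with 24 at an unadjusted p under 0.05. This count was 0 without replicate 1, 2 or 3, 1 on the percent scale and 0 with the median over sites. The highest levels that did not pass were 60.3% ± 7.64 for REST_tile6_BHLHE40, 58.7% ± 10.2 for REST_tile2_BHLHE40, 57.5% ± 2.30 for REST_tile2_BHLHE40_r, 56.7% ± 2.76 for REST_tile3_BANP and 56.5% ± 3.49 for REST_tile3_BHLHE40_r (SD, n = 3 each).

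**Figure D3:**
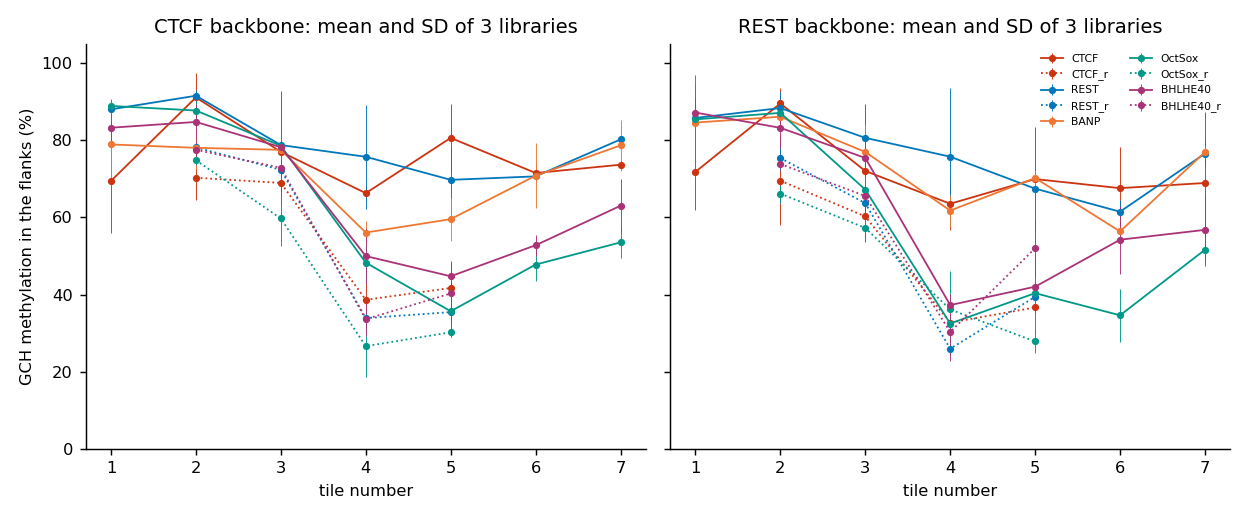
Methylation in the flanks (vertical axis, %) by tile number (horizontal axis) for each motif (solid lines) and its partner (dotted lines) in both backbones, as means with SD of 3 libraries. In the CTCF backbone the OctSox flanks go from 88.9% at tile 1 to 35.7% at tile 5, and the REST flanks stay at or above 69.8%.

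NRF1, an activator of promoters whose binding is sensitive to CpG methylation, was measured with its partner in 2 sequences in 3 libraries. In the non-nucleosomal sequence, the flanks of NRF1 were 58.9% ± 1.92 and those of the partner 48.9% ± 3.85 (SD, n = 3 each). The difference was 10 ± 5.77 percentage points, with the same sign in 3 of 3 libraries. The windows were 56.0% ± 5.29 and 66.7% ± 5.77 (SD, n = 3 each). They held 5 sites for NRF1 and 1 for the partner, so the 2 values do not cover the same positions. In the unphased sequence both flanks were 34.4%, with SDs of 3.85 and 6.94 and below the 47.2% of the same NRF1 construct in its unphased pool, and the amplicon was 37.7% ± 4.09 against 44.2% ± 3.66 (SD, n = 3 each), −6.45 ± 1.71 percentage points in 3 of 3 libraries. The exact sign test of 3 libraries cannot go below p = 0.25, and no other test of these pairs was run. Against the pool median 4 of 4 constructs passed limma's test, 2 higher and 2 lower, or 2 of 4 without replicate 3, but this reference mixes both sequences. At CGH sites of the same libraries, which the design took to read CpG methylation, the amplicon was 32.0% ± 3.24 for NRF1 and 38.8% ± 2.04 for its partner in the unphased sequence, and 16.1% ± 1.11 and 15.9% ± 1.79 in the non-nucleosomal one (SD, n = 3 each). With 4 constructs no correlation of GCH with CGH levels is given.

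The REST motif at tile 5 of the CTCF backbone was compared between REST_NP and REST_ES, a pair of names that the labels do not spell out. The labels give embryonic stem cells as the cell type of both groups, so what distinguished REST_NP is not known from them. Flanks were 32.5% ± 5.0 in REST_NP and 64.2% ± 7.64 in REST_ES (SD, n = 3 each), lower by more than the spread between replicates. The motif window was 23.3% ± 8.78 in REST_NP and 6.67% ± 1.44 in REST_ES, while the mean of the whole amplicon was 46.5% ± 2.72 and 46.8% ± 2.80 (SD, n = 3 each). The median over its sites was 30%, 30% and 40% in the REST_NP libraries and 70%, 50% and 60% in those of REST_ES. That is a difference of −26.7 percentage points, so the close means do not show an unchanged amplicon. At single sites beside the window, methylation was lower in REST_NP at position 253, at 30% ± 0 against 63.3% ± 5.77 (limma adjusted p = 0.00381, and 0.0428 with the replicate number as a block; SD, n = 3 each). Inside the window it was higher at position 220, at 20% ± 10 against 0% ± 0 (limma adjusted p = 0.00402, and 0.0428 with the block; SD, n = 3 each). Position 243, at 23.3% ± 5.77 against 70% ± 10, and position 213, at 23.3% ± 5.77 against 10% ± 0 (SD, n = 3 each), passed without the block (limma adjusted p = 0.0111 and 0.0161) but not with it (adjusted p = 0.0609 for both).

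The flank difference of −31.7 percentage points had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allow. In limma 6 of 23 sites passed, 4 higher and 2 lower, with 8 at an unadjusted p under 0.05, and 3 passed with the replicate number as a block (positions 96, 220 and 253). Of the 6, positions 96, 253 and 299 passed without replicate 1, 96 and 220 without replicate 2, and 96 and 213 without replicate 3, so only position 96 passed each time. The values in these files were rounded to 1 decimal of a fraction, so that a site has steps of 10 percentage points and some groups have an SD of 0. Of the 4 higher sites, that at position 96 (90% against 80%) had an SD of 0 in both groups, and no weight can be put on its p.

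The BANP motif at the same tile was compared between dTAG, a name used for ligands that degrade a tagged protein, and the solvent DMSO. The labels do not say which protein was tagged. Flanks were 43.8% ± 23.0 with dTAG and 60% ± 3.54 with DMSO (SD, n = 2 each). In replicate 1 they were 27.5% with dTAG and 57.5% with DMSO, and in replicate 2 they were 60% and 62.5%. The window was 38.3% in both groups, with SDs of 25.9 and 11.8 (n = 2 each). In limma 0 of 22 sites passed, with 0 at an unadjusted p under 0.05, and in simulated data of this size 1.25% of changes of 1.5 (log2) were found, so a difference was not detectable here. The flank difference was −2.5 percentage points without the replicates numbered 1 and −30.0 without those numbered 2. With 2 against 2, an exact permutation test cannot go below p = 0.3333.

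**Figure D4:**
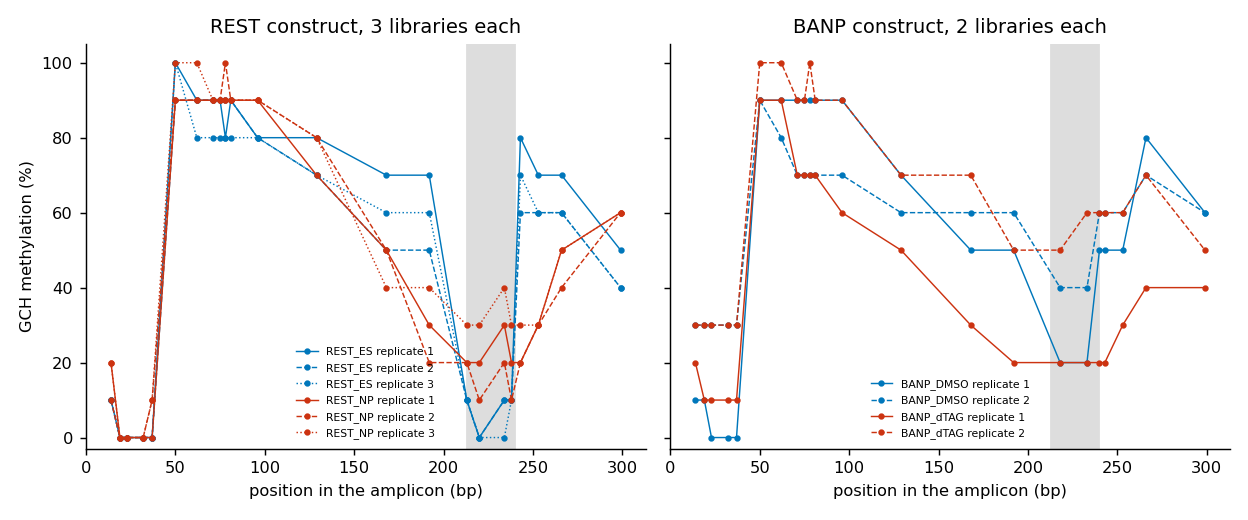
GCH methylation (vertical axis, %) along the amplicon (horizontal axis, bp) for each library of the REST construct (REST_ES and REST_NP) and of the BANP construct (DMSO and dTAG), the motif window in grey. The REST flanks average 64.2% in REST_ES and 32.5% in REST_NP.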

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

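The tests of motif effects at flanks and in windows, and all tests of explanations in this part, were chosen after the results were seen. Between the nuc and non_nuc contexts, the effect of a motif on the flanks differed by 1.672 (log2) for CTCF, 1.201 for REST, −1.319 for ARNTL and −1.277 for SRF, as a limma test of the difference itself found. In the windows it differed by 2.022 for CTCF, 2.068 for REST, 2.07 for TRP53, 1.452 for OctSox, 1.385 for BANP, 1.338 for RFX2 and 1.068 for MTF1, relative to a window without a motif that held 1 site in each class. Here a positive value is a smaller drop in nuc, where that window was 28.3%, against 67.1% in non_nuc. The CTCF windows were 15.5% and 19.5%, so the differences rest largely on the window without a motif. At the flanks 4 motifs differed, of which 2, 3 and 2 did without replicates 1, 2 and 3, and only CTCF each time. In the windows 8 differed, and 13, 5 and 3 did without replicates 1, 2 and 3. The pools of nuc and non_nuc are different libraries, so the context and its libraries are confounded. The flank without a motif was 45.9% in nuc and 60.5% in non_nuc, so the room for a gain also differed.

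The tests of 3 libraries against 3 were repeated over the 10 splits of the 6 libraries, which are too few for a share under 0.05. For nuc against non_nuc over the amplicon, the real split gave 0 calls in limma (2 at an unadjusted p under 0.05), and all 10 splits gave as many. In the other tests 1 of 10 splits, the real one, gave as many calls as the real one. The real counts were 5 and 14 for non_nuc flanks and windows, 3 and 5 against the partners, 8 and 6 for nuc flanks and windows, 5 and 3 against the partners, 4 and 8 for nuc against non_nuc flanks and windows, and 18 and 19 for tiles. The highest count of another split in these was 0. For REST_NP against REST_ES the real counts were 6 at GCH sites and 7 at CGH sites, and the highest other was 1 in both, also 1 and 0 among the 4 splits that part all pairs. The CGH values were equal to GCH values wherever both could be compared, so these are not separate evidence.

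The dTAG libraries of BANP differed from each other, with flanks at 27.5% and 60%. In the libraries numbered 2, anchor sites were 30.0% methylated in both DMSO and dTAG, against 4.0% and 12% in those numbered 1. If the anchor level were a background shared by all sites, raising that of dTAG replicate 1 from 12% to 30.0% would give 42.3% at the flanks. This is 17.7 percentage points below the observed 60%. The assumption was not tested, and at position 96 DMSO replicate 2 was at 70%, below the 90% of DMSO replicate 1. The value therefore does not bound what a raised background could account for, and 1 library does not decide it. The flank of dTAG replicate 2 lay at −2.5 percentage points from DMSO replicate 2, as a library that kept the factor or carries a wrong label would also give. Its window lay at 56.7%, above the 46.7% of DMSO replicate 2, so this likeness holds for the flanks only. With 1 library per replicate and treatment these explanations cannot be told apart, and a biological effect of dTAG stays untested.

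The REST windows of the tiles ranged from 4.94% to 6.30% in pools 2 and 4 and from 10.6% to 39.8% in pool 6, where the anchor sites ranged from 19.2% to 40.2% and 3 of 3 libraries had the same rank by window and anchor level, against 1 of 3 in pool 4 and 0 of 3 in pool 2. A library background read at the anchor sites could raise both, but 3 libraries cannot decide it, and the rank test replaced a correlation over all 9 libraries, which had favoured the background, because the libraries cluster by pool. Of the REST constructs in that pool, CTCF_tile5_REST was also measured in REST_ES, with a window of 6.67% ± 1.44 and anchor sites at 2.0%, against 26.8% ± 20.1 and 24.2% in pool 6 (SD, n = 3 each). That difference is about as large as the spread in pool 6, so it does not tell whether the sequence of this construct is the source, and no biological explanation was tested.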

How the results depend on the processing

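The tests on flanks and windows, the offset of 0.05, flanks of 20 and 60 bp and the CGH sites were chosen after the results were seen, and the other alternatives were planned. Not run, for want of read counts, were the coverage minimums, the larger count added to M-values and edgeR or quasi-binomial models, and for unphased constructs each replicate left out, which leaves no residual degrees of freedom. Of 1275 values of single constructs or sites under an alternative, 1100 kept their side of the threshold, 170 kept their direction and no longer passed, and 5 reversed: with the median over sites non_nucleosomal_NRF1_r (−0.24) and unphased_NRF1_r (0.24) among NRF1_pool constructs, without replicate 1 unphased_TFAP4 (0.18, against −0.97 without replicate 2) among unphased flanks, and with a flank of 20 bp CTCF_tile4_CTCF (−0.22) and REST_tile4_CTCF (−0.27) among tiles flanks (all log2). The 1275 include unphased flanks and windows without a replicate, where each construct has 1 library. They also include pool median fits of the unphased, tiles and NRF1 classes, where the median was already the reference. Values kept in these fits say nothing about stability, so 1100 overstates it. The causes below were not tested unless named. Counts past the threshold changed by over 1.5 times as follows. With window sites in place of the amplicon, unphased constructs went from 12 to 29. With the median over sites 8 passed, which is not a change of over 1.5 times, but only 6 of the 12 were among them. For non_nuc constructs, 2 as reported, the median over sites gave 8, the pool median reference 0, flank sites 13, window sites 14 and leaving out a replicate 0 to 2, the 1 call without replicate 3 being another construct. The pool of the 2 reported, ARNTL and SRF, has no control, so with the pool median reference their own differences stayed the same. For nuc constructs, 0 as reported in limma (1 at an unadjusted p under 0.05), they were 7 with the median, 6 with flank sites and 8 with window sites. For tiles positions, 2 as reported, they were 1 on the percent scale, 0 with the median, 44 with flank sites, 43 with window sites and 0 without any 1 replicate. NRF1_pool constructs, 4 as reported, were 2 to 4 without a replicate. For nuc against non_nuc, 0 as reported in limma (2 at an unadjusted p under 0.05), the median gave 7, flank sites 2, window sites 8 and leaving out a replicate 0 to 1. Leaving out a replicate gave 82 to 87 for unphased flanks (46 as reported) and 110 to 110 for unphased windows (59), where the spread then comes only from the 2 libraries without a motif, so these counts say nothing about stability. It gave 5 to 10 for non_nuc flanks (5), 2 to 3 for nuc against non_nuc flanks (4), 4 to 11 for nuc windows (6), 3 to 13 for nuc against non_nuc windows (8), 7 to 11 for tiles windows (19) and 2 to 5 for REST NP against ES (6). Of the 6 REST sites 3, 2 and 2 passed without replicates 1, 2 and 3, and the other calls were other sites, and of the 4 flanks of nuc against non_nuc 2, 3 and 2 passed. The REST flank difference was −21.3 percentage points at CGH sites, which are no separate evidence.

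With the replicate number as a block, REST NP against ES went from 6 to 3, unphased windows from 59 to 27 and tiles windows from 19 to 11, and the paired fits changed no other count by over 1.5 times. By the labels the libraries share only a number: for nuc against non_nuc same-numbered libraries correlated at −0.195 to 0.0557, where the block left the count at 0 in limma (1 at an unadjusted p under 0.05), and for BANP at 0.103 in 2 pairs, where it left 0 (0 at an unadjusted p under 0.05). Unknown depth limits the precision of each value.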

Other observations

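The tests in this part were chosen after the results were seen. A hypothesis is that CTCF and REST gain more accessibility over their partners where the backbone is less accessible, at tiles 4 and 5, than at tiles 2 and 3, and that OctSox and BHLHE40 do not. The change in flank gain was 26.9 percentage points higher for the first pair, with 16.2 to 28.2 for CTCF and REST and −11.1 to 4.13 for OctSox and BHLHE40. Both groupings were made from these values, and 2 motifs against 2 cannot give an exact permutation p below 0.3333, so the hypothesis stays untested. A permutation that took each motif and backbone as independent was run first and dropped. With a flank of 20 bp, the effect against the partner at tile 4 was −0.22 (log2) for CTCF_tile4_CTCF and −0.27 for REST_tile4_CTCF, so the pattern may depend on the flank chosen. The REST change rests largely on pool 6, which held the REST constructs of both backbones at tiles 3 and 4 and of the CTCF backbone at tile 5, with partners in other pools. Anchor sites of the REST constructs in it ranged from 19.2% to 40.2%, so a raised background may add to those gains. Pool 6 also held either the motif or the partner of OctSox pairs at tiles 3, 4 and 5, so this background may enter the OctSox change too. The REST pair at tile 5 within a pool gained 28.1 percentage points, against 13.4 and 12.97 at tile 2.

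The CGH files of BANP and REST hold positions 1 base before a GCH position in 100% of cases. Of the values that both kinds of file hold for the same dinucleotide, 128 of 128 were equal, with a largest difference of 0, which is what a hypothesis that these files read the same GpC sites 1 base earlier predicts. The CGH levels of these groups may therefore not be a separate measurement of CpG methylation, and they are not read as one. In the NRF1 libraries the CGH positions differ from the GCH positions.

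The names ending in "_r" could stand for the reverse complement of a motif. The test used the share of window positions shared with the partner, mirrored minus not mirrored, over 14 unphased pairs, and gave 0 ± 9.81 percentage points (SD; permutation p = 1.0), so the positions leave this open. It was the last of 4 forms tried. Exact mirroring held in 0 of 58 pairs, and containment in 0 of 36, but both were too strict, because GCH leaves out GC followed by G. The mirrored share was 69.1% against 55.5% for mismatched partners (one-sided permutation p = 0.0001, the smallest possible), but unmirrored positions gave 73.7% against 54.2%, so that form was not specific. A reverse complement keeps the same double-stranded site, so the response should stay. Unphased flanks beside the partners of BANP, CTCF and REST were 48.5% ± 2.57, 42.1% ± 2.82 and 49.0% ± 8.92 (SD, n = 2 each), against 76.7%, 87.5% and 83.4%. In nuc they were 31.8%, 44.4% and 47.6%, against 71.5%, 89.5% and 83.9%. These values argue against a reverse complement for the 3 motifs, while the other unphased pairs did not pass at the flanks.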
